A study of Mus musculus with 5 samples.

How the data were processed

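RNA was measured by sequencing in quiescent satellite cells sorted from wild-type mice (2 libraries) and mdx mice (3 libraries). Per the labels' protocols, each library was made from between 10000 and 20000 sorted cells with a stranded total RNA kit for low input. The submitters' processing notes name STAR 2.6.1d (an aligner), featureCounts 1.6.3 from Subread (a read counter), DESeq2 1.18.1 and the mouse build mm10. The strand setting of the counting, the treatment of duplicate reads and reads mapping to several places, and any filter on genes are not given in the sources used here.

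The deposited table holds 1 column per library and 22683 genes, with Ensembl gene identifiers, symbols and mm10 coordinates. Its values are whole numbers, but they are not raw counts: the unit is treated here as a score, the deposited normalized count, that is, reads per gene divided by 1 size factor per library and rounded by the authors. The source of this statement is the values themselves. The median ratio to the gene means was equal in all 5 columns (0.9996 to 1.0004) although the totals differed. In mdx replicate 1, 6 of the whole numbers from 1 to 30 never occurred, as happens when counts are multiplied by a constant above 1 and rounded. The worth of 1 read was estimated from how often each whole number occurred, at 0.891 and 0.861 in the wild-type libraries and 1.246, 0.937 and 0.94 in mdx 1, 2 and 3. Where a read was worth under 1, rounding had merged neighbouring counts, so raw counts could not be restored. The design fixed before the data were examined had assumed raw counts and a count model. Since the values were normalized, that model was replaced by one on the log scale. The pseudocount and filter were set at that point, before any test was run.

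Values were transformed to log2(normalized count + 2). Genes with a value of at least 10 in at least 2 libraries were tested, which left 18199. Genotype was the only term of a linear model fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation along the mean expression trend and robust to outlying variances. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Fold changes are differences between group means of log2(normalized count + 2), so a fold can lie above or below the ratio of the printed means. The added 2 pulls the folds of genes with low values toward no change. Intervals are 95% intervals from the same fit. Because the values are scaled to equal median ratios, a difference between genotypes is relative to the typical gene, and the median log2 fold change over all tested genes was 0.135.

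Before the data were examined, 44 gene lists were fixed from textbook knowledge, covering stem cell and muscle programs, cell death, chromatin, signalling, metabolism, RNA quality and the other cell types a sort from muscle could hold. The 43 lists with at least 5 tested genes were compared with all other genes by camera (limma) with a preset correlation between genes of 0.01, adjusted over the 43 lists. The adipocyte list, with 4 tested genes, was not tested as a list. Each list was also tested with an estimated correlation, and with fry, which asks whether the genes of a list move without comparing them with other genes. The version with an estimated correlation also judges each list against the spread of few libraries, so a list can fail it whatever its correlation.

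Named genes follow a rule fixed in advance. Dmd, Ripk3, Ripk1, Mlkl, Chd4, Pax7, Myod1 and Myog are named whatever their test. In each direction, the 8 called genes with the largest fold change and the 4 with the smallest p are named, given at least 10 CPM (of the normalized counts) in the higher group, no overlap of libraries between the genotypes, and a symbol that is not a clone, model, pseudogene or immunoglobulin segment name. For each list, up to 4 called members with the smallest p are named, or up to 2 members where none was called. Any other gene is described in the text as chosen after its values were seen. Some genes that meet the rule are not reported here.

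Transcript length and GC content were taken from the longest annotated transcript of each gene in GENCODE release M21, in which 22649 of the 22683 identifiers were found, 17202 of them with the same chromosome, start and end. The steps were tested on simulated tables, with 200 genes changed per table, none of them of low mean. Real genes supplied a common mean for both genotypes before the changes, and spreads averaged over genes of similar mean. Genes were drawn independently. In 5 such tables of about 17881 tested genes, 15.8% of genes with a 2-fold change, 58.8% of those with a 4-fold change and 77.6% of those with a 16-fold change were called. Of all calls in these tables, 3.07% were false. These rates need not hold for the real libraries, where genes are correlated and 24.9% of tested genes were called. The length correction was rewritten once, because the first version left part of a planted length trend in simulated data.

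Alternatives fixed before the data were examined were trimmed-mean-of-M-values scaling (unweighted, trimming 30% of ratios and 5% of averages at each end), upper-quartile scaling, no filter, a stricter filter of 5 CPM, the replicate number as a block, a minimum fold of 1.5, leaving out each library in turn, and the other list tests. Chosen after the data were seen were pseudocounts of 1 and 10, quantile normalization, removal of each library's trend with transcript length and GC content (lowess span 0.3), a fit on protein-coding genes outside the mitochondrial genome, and library weights.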

Results

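Satellite cells are the stem cells of skeletal muscle, which rest between the muscle fiber and its basement membrane until injury. Cells described as quiescent were sorted from wild-type mice and from mdx mice, which carry a mutation in the dystrophin gene and model Duchenne muscular dystrophy. Total RNA was sequenced from 2 wild-type and 3 mdx libraries, and gene expression is given as normalized read counts. Means are given ± SD, with n = 2 for wild type and n = 3 for mdx. The libraries summed to 15217054 and 16825045 normalized counts in wild type and to 15930638, 12473348 and 13932270 in mdx 1, 2 and 3. The corresponding read numbers, estimated from the spacing of the rounded values, were 17.1 M and 19.6 M in wild type and 12.8 M, 13.3 M and 14.8 M in mdx. Across genes, log2 values correlated with Pearson's r = 0.859 between the wild-type libraries, 0.838 to 0.862 between mdx libraries and 0.607 to 0.686 between genotypes. The labels do not say whether the libraries came from separate animals, so the p-values measure the spread between these libraries, which may be technical. Sex, age, strain, muscle, sorting gate and batch are not given in the sources used here. Sex-linked transcripts, given below, mark the wild-type libraries as female and the mdx libraries as male, so every comparison is also one of sex.

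The series compared satellite cells of dystrophic and healthy muscle, and its title names necroptosis, a regulated form of cell death, and epigenetic suppression. In mdx, 45 of 51 tested genes of collagens and matrix, 20 of 22 endothelial, 22 of 29 macrophage, 21 of 40 cell cycle and 15 of 28 myogenic genes rose. Falls were called for 244 of 357 small nucleolar and nuclear RNAs, 72 of 77 ribosomal protein genes, 33 of 74 nuclear genes of the respiratory chain and 9 of 24 cholesterol synthesis genes. The lists among these passed camera with the preset correlation between genes and did not with an estimated one (adjusted p = 0.175 to 0.383). None of these rises and falls could be told apart from a difference in sex or RNA preparation between the genotypes' libraries. In the limma fit, 2659 genes were higher and 1868 lower in mdx, together 24.9% of the 18199 genes tested. The largest rises under the naming rule included Thbs4, Postn and Ptprb, a receptor phosphatase gene of vascular endothelium listed at 0 in wild type and at 7591, 7030 and 5276 in mdx. Aqp1, encoding a water channel, was among the genes with the smallest p, rising 109-fold from 51.5 ± 9.19 to 5794 ± 446 (limma adjusted p = 1.19e-06). At an unadjusted p under 0.05 there were 6933 genes. In CPM, that is, normalized counts rescaled to equal library totals, the libraries of the genotypes did not overlap for 50.7% of tested genes, against 20% by chance. Of the called genes, 558 were listed at 0 in both wild-type libraries and 131 in all mdx libraries. With 1 library left out, the counts were 3308 higher and 1853 lower without wild type 1, 2726 and 1552 without wild type 2, 1709 and 1266 without mdx 1, 1491 and 1186 without mdx 2, and 1450 and 1112 without mdx 3. The share of calls that were higher in mdx was 58.7%. It was 44.3% (1719 higher, 2159 lower) after removal of each library's trend with transcript length and GC content.

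Of the 43 gene lists tested, 24 passed the camera threshold, 18 of them higher and 6 lower in mdx. With an estimated correlation between genes, 0 of the 43 passed, 8 had an unadjusted camera p under 0.05, and fry called 31. The plot of the lists shows the spread of fold changes within each.

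**Figure D1:**
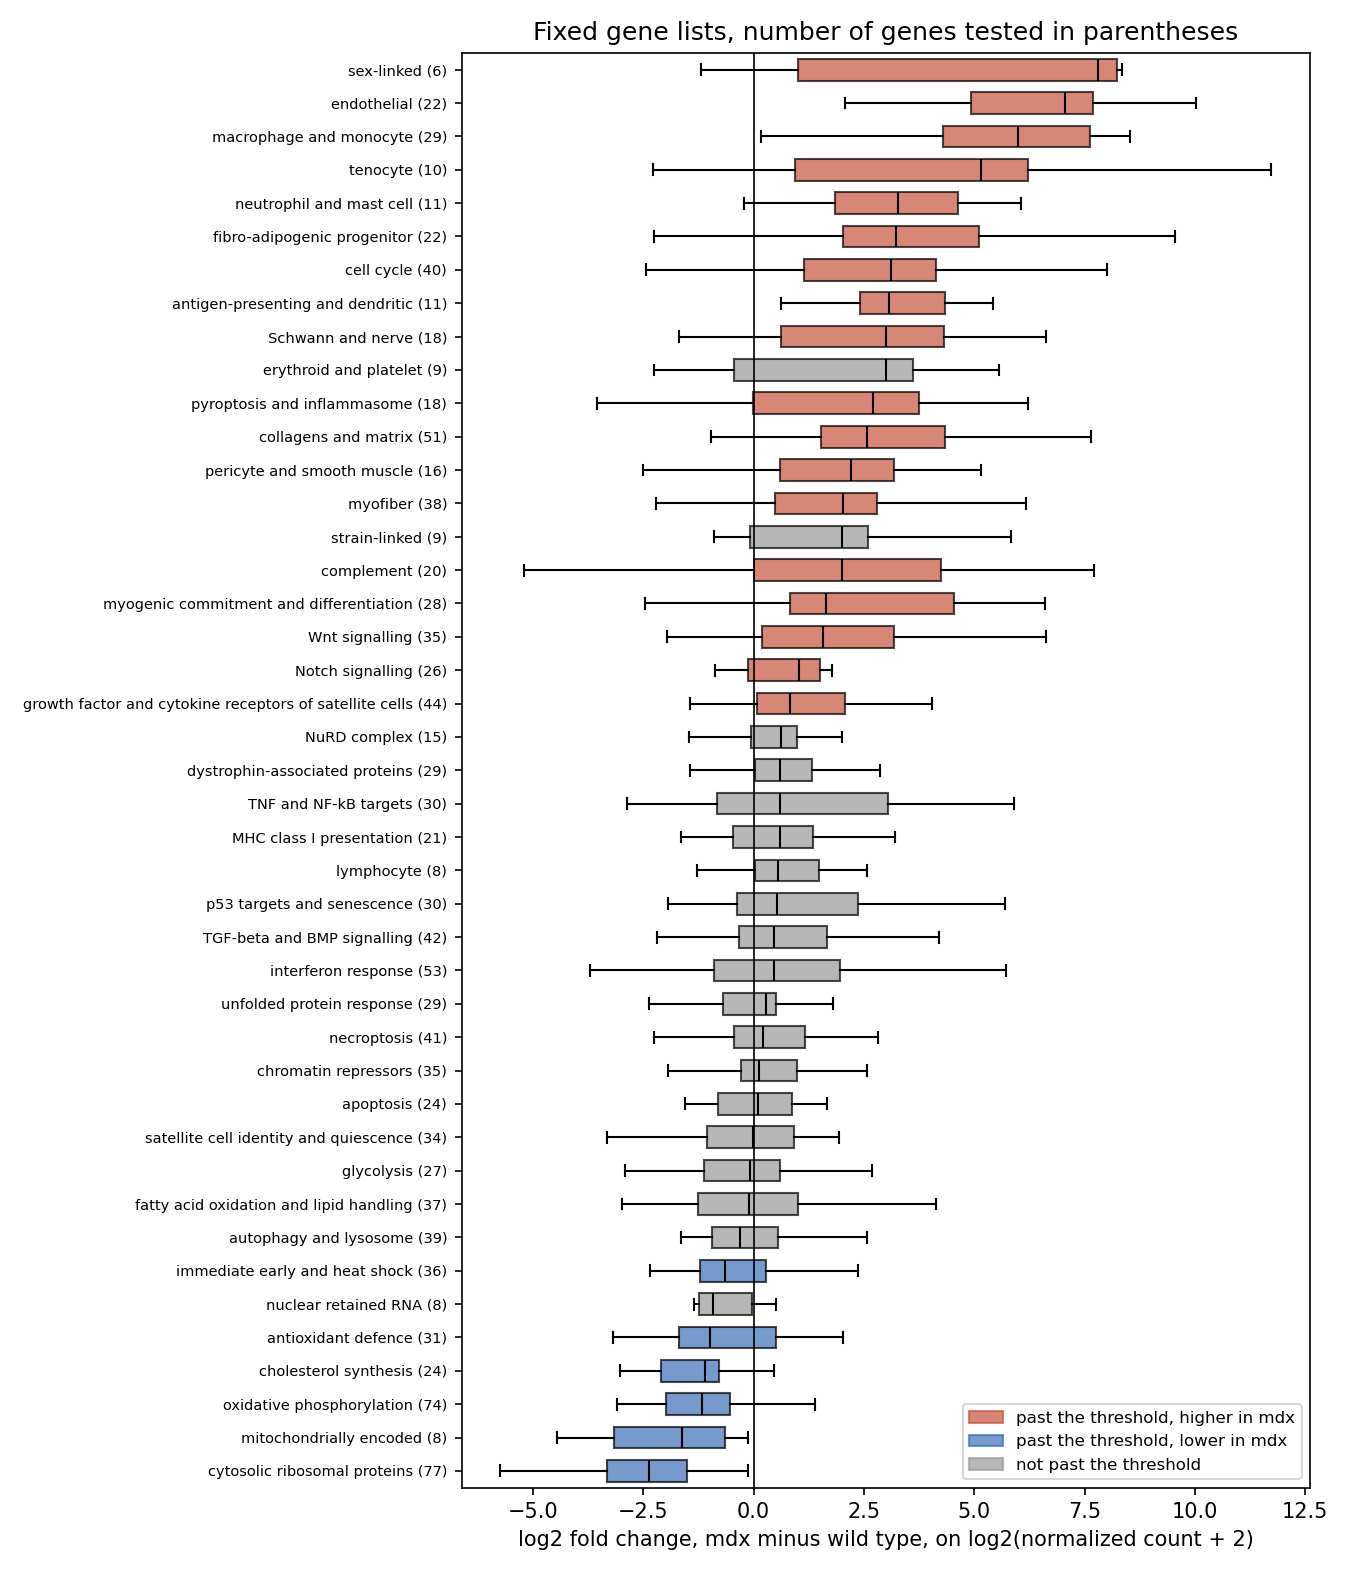
Log2 fold changes (mdx minus wild type, on log2(normalized count + 2)) of the members of each of the 43 fixed lists; boxes span the quartiles, the line is the median and whiskers reach the farthest gene within 1.5 box lengths. Red lists (18) passed the camera threshold higher in mdx, blue lists (6) lower, and gray lists (19) did not pass.

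Dmd, which encodes dystrophin and carries the mdx mutation, lies on chromosome X, 82948903 to 85206141 (mm10). Its normalized counts were 11826 and 9266 in the wild-type libraries and 4642, 4116 and 3700 in mdx 1, 2 and 3. The log2 fold change was −1.34 (SE 0.18, 95% interval −1.75 to −0.93, limma adjusted p = 0.00099), and all 3 mdx libraries lay below both wild-type libraries. Quantile normalization gave a smaller log2 fold change of −0.83 (limma adjusted p = 0.0128). Among the 29 tested genes for dystrophin, its homolog utrophin and their partners at the membrane, 9 rose, 2 fell and 18 did not pass. The list as a whole did not pass (camera adjusted p = 0.108, but 0.0218 after quantile normalization), with 9 higher and 2 lower when adjusted over the list alone. Plec, encoding the cytoskeletal linker plectin, rose 9.85-fold from 2034 ± 185 to 20255 ± 3817 (limma adjusted p = 1.38e-05). Sntb2, encoding a syntrophin, rose 2.6-fold. Utrn, encoding utrophin, rose 2.33-fold from 4729 ± 75.0 to 11079 ± 1289 (limma adjusted p = 0.000865), but its log2 fold change went from 1.22 to 0.33 and was no longer called after length and GC correction (limma adjusted p = 0.127).

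Genes of the resting stem cell state moved both ways. Of 34 tested genes of satellite cell identity and quiescence, 11 rose, 13 fell and 10 did not pass, and the list did not pass (camera adjusted p = 0.588). There were 13 higher and 14 lower when adjusted over the list alone. Pax7, the transcription factor that marks satellite cells (chromosome 4, 139737062 to 139833528), had normalized counts of 8374 ± 1032 in wild type and 12502 ± 2629 in mdx and did not pass (limma adjusted p = 0.0698). It passed without wild type 1 (limma adjusted p = 0.010), with no filter (0.0354) and after quantile normalization (log2 fold change 1.34, 0.00111). Its log2 fold change of 0.56 turned to −0.50 after length and GC correction (limma adjusted p = 0.0788). Sdc4, encoding the surface proteoglycan syndecan-4, fell 10.0-fold from 29359.5 ± 2159 to 2937 ± 315 (limma adjusted p = 7.38e-06). Cd34, encoding a surface sialomucin used to sort satellite cells, fell 3.78-fold from 6481 ± 622 to 1715 ± 195. Cdkn1c, encoding the cyclin-dependent kinase inhibitor p57, rose 20.9-fold from 71.5 ± 44.5 to 1402 ± 287 (limma adjusted p = 0.000203). Rgs5, a regulator of G-protein signalling that is also a pericyte marker, rose 33.2-fold (limma adjusted p = 0.000274). Without wild type 1 or 2, the log2 fold changes were 5.04 and 3.72 for Cdkn1c (from 4.38) and 4.0 and 6.10 for Rgs5 (from 5.05). After length and GC correction the list passed as lower in mdx (camera adjusted p = 0.0164).

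Genes of myogenic commitment and differentiation were higher in mdx: 15 of 28 tested rose, 1 (Tnnt1, a troponin gene chosen after its values were seen) fell and 12 did not pass. The list had a median log2 fold change of 1.64, or 1.48 over the 25 members above 0 in wild type. Its camera adjusted p = 3.77e-05 with the preset correlation and adjusted p = 0.281 with an estimated correlation. Adjusted over the list alone, 17 higher and 1 lower were called. Myod1, the myogenic determination factor (chromosome 7, 46376474 to 46379099), rose 3.26-fold from 263 ± 90.5 to 843 ± 116 (SE of log2 0.33, limma adjusted p = 0.00592). The call ended without mdx 3 (limma adjusted p = 0.0521) and after length and GC correction, where the log2 fold change was 0.98 instead of 1.71 (limma adjusted p = 0.0618), and with the replicate number as a block (0.0598). Myog, encoding myogenin, which drives differentiation (chromosome 1, 134289989 to 134292548), had 91 and 1 normalized counts in the wild-type libraries and 1806, 1605 and 1491 in mdx. Its log2 fold change was 6.61 (SE 1.13, limma adjusted p = 0.00343), and 9.09 or 4.13 without wild type 1 or 2. Without mdx 1, 2 or 3, limma adjusted p = 0.0553, 0.0519 and 0.0564. Igf2, an insulin-like growth factor gene, rose 6.73-fold from 1434 ± 349 to 9613 ± 1679.7 (limma adjusted p = 5.94e-05), and Mef2c, encoding a muscle transcription factor, from 5.5 ± 2.12 to 612 ± 155.

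Transcripts abundant in muscle fibers were higher as well. Of 38 tested myofiber genes, 15 rose, 1 (Myh7, encoding slow myosin, chosen after its values were seen) fell and 22 did not pass. Members had a median log2 fold change of 2.02 (1.82 over the 36 members above 0 in wild type), with camera adjusted p = 0.000425 and adjusted p = 0.353 with an estimated correlation. Calls adjusted over the list alone were 16 higher and 1 lower. Ttn, encoding the giant sarcomere protein titin, rose 16.9-fold from 2288 ± 265 to 41864 ± 20929 (limma adjusted p = 9.32e-05). Neb, encoding nebulin, rose 12.1-fold and Tpm2, encoding a tropomyosin, 5.81-fold. Of the tested myofiber genes, 30 had a mean of at least 10 in wild type.

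Cell cycle genes were higher in mdx, with 21 of 40 risen, 1 fallen and 18 not passing. Adjusted over the list alone, 23 higher and 1 lower were called. Their median log2 fold change was 3.10 (2.58 over the 35 members above 0 in wild type), with camera adjusted p = 1.37e-05 and adjusted p = 0.383 with an estimated correlation. Mcm2, encoding a subunit of the replicative helicase, rose 8.59-fold from 92 ± 31.1 to 808 ± 256 (limma adjusted p = 0.00090). Top2a, encoding the topoisomerase of dividing cells, rose 12.1-fold, and Cenpf, encoding a kinetochore protein, 14.8-fold. Pcna, encoding the sliding clamp of DNA polymerases, fell 5.4-fold from 3064 ± 385 to 581 ± 167 (limma adjusted p = 0.000474). In the mdx libraries where cell cycle, myogenic and myofiber genes were higher, so were endothelial markers (median log2 fold change 7.05) and macrophage markers (5.98).

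**Figure D2:**
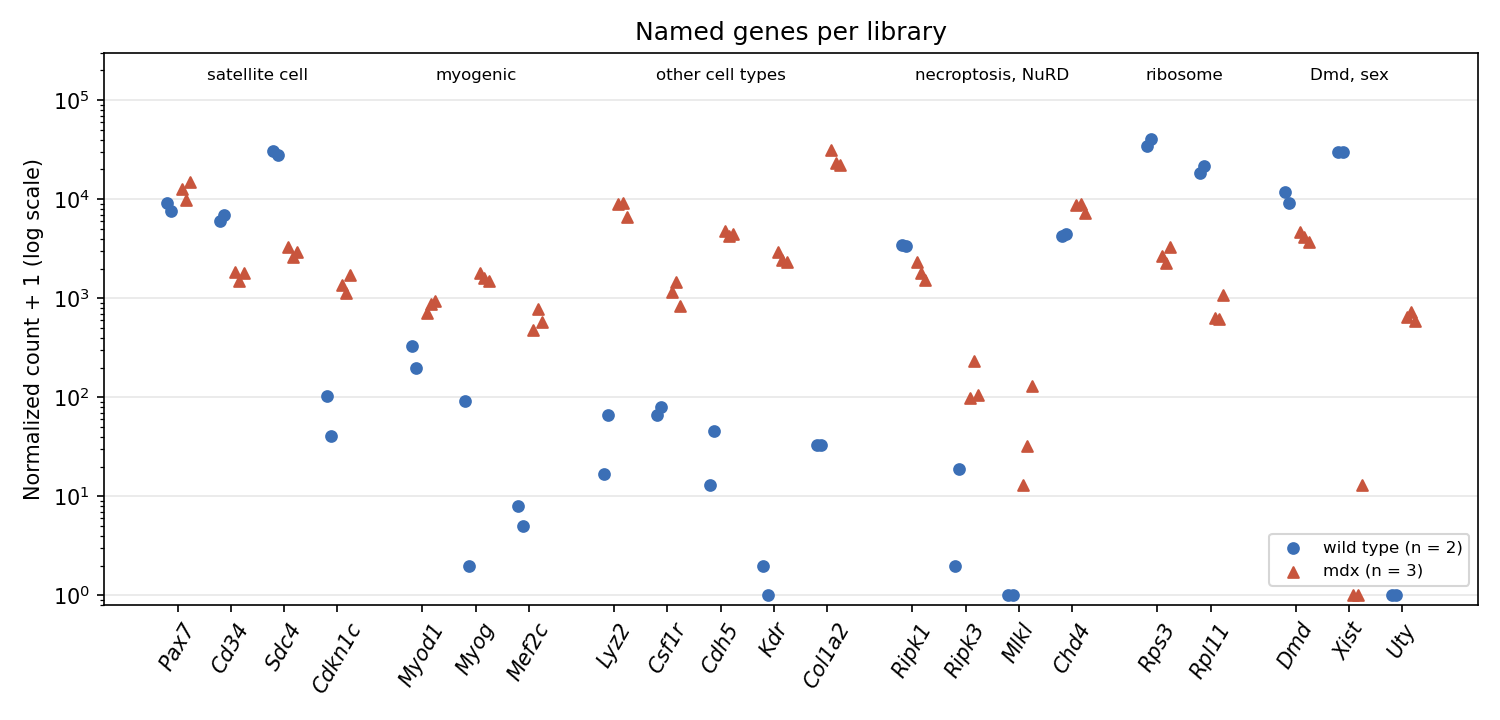
Normalized counts plus 1 (log scale) of named genes in each library, with blue circles for wild type (n = 2) and red triangles for mdx (n = 3). Dmd, Sdc4, Cd34, Ripk1, Rps3, Rpl11 and Xist lie lower in all 3 mdx libraries than in both wild-type libraries, and Myog, Lyz2, Kdr, Col1a2, Chd4 and Uty higher.

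Markers of other cell types of muscle were higher in mdx, several of them from near 0. Over 11 lists of such markers, 96 of 159 tested genes rose and 5 fell. Among endothelial markers, 20 of 22 rose and Tek, encoding an angiopoietin receptor and chosen after its values were seen, fell (camera adjusted p = 3.73e-12, adjusted p = 0.175 with an estimated correlation). There were 21 higher and 1 lower when adjusted over the list alone. Kdr, encoding the main receptor for vascular endothelial growth factor, had 1 and 0 normalized counts in wild type and 2947, 2424 and 2301 in mdx. Cdh5, encoding the endothelial cadherin, rose 176-fold from 28.5 ± 23.3 to 4526 ± 284 (limma adjusted p = 1.77e-05), and Pecam1, encoding an endothelial junction protein, rose 23.3-fold. Macrophage and monocyte markers rose in 22 of 29 cases (camera adjusted p = 4.50e-13, adjusted p = 0.245 with an estimated correlation). Adjusted over the list alone, 24 higher were called. Lyz2, encoding lysozyme, rose 234-fold from 41 ± 35.4 to 8264 ± 1418 (limma adjusted p = 1.69e-05), and Csf1r, encoding the receptor for macrophage colony-stimulating factor, rose 15.2-fold from 72.5 ± 9.19 to 1155 ± 321. Without wild type 1 or 2, the log2 fold changes were 6.59 and 8.34 for Cdh5 (from 7.46) and 6.91 and 8.83 for Lyz2 (from 7.87). The median log2 fold change was 7.05 for endothelial markers (6.78 over the 14 above 0 in wild type) and 5.98 for macrophage markers (4.21 over 12).

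Mesenchymal and matrix genes were higher in mdx. Of 51 genes of collagens and matrix, 45 rose, 1 (Thbs2, encoding a thrombospondin, chosen after its values were seen) fell and 5 did not pass (camera adjusted p = 4.30e-15, adjusted p = 0.245 with an estimated correlation). The median log2 fold change was 2.57, or 2.26 over the 47 members above 0 in wild type, and 45 higher and 1 lower were called when adjusted over the list alone. Col1a2, encoding a chain of type I collagen (chromosome 6, 4505493 to 4541544), had 32 and 32 normalized counts in wild type and 31652, 23470 and 22299 in mdx (limma adjusted p = 8.15e-08). Fn1, encoding fibronectin, rose 57.7-fold from 236 ± 75.7 to 13494 ± 1956 (limma adjusted p = 2.74e-06), and Col6a3, encoding a collagen VI chain, went from 7 and 6 to 8700, 7231 and 6236. Postn, encoding the matrix protein periostin, was listed at 0 in both wild-type libraries and at 4168, 5731 and 4473 in mdx. Markers of fibro-adipogenic progenitors, the mesenchymal cells between muscle fibers, rose in 17 of 22 cases, with a median log2 fold change of 3.22 (2.95 over the 20 above 0 in wild type; camera adjusted p = 5.62e-06, adjusted p = 0.342 with an estimated correlation). Calls adjusted over the list alone were 18 higher and 2 lower. The exception Dpt, encoding dermatopontin, fell 4.8-fold from 9523 ± 215 to 2002 ± 345 (limma adjusted p = 9.08e-05), while Smoc2 rose 22.5-fold.

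Markers of further cell types were also higher. Tenocyte markers rose in 7 of 10 cases (camera adjusted p = 0.00287, adjusted p = 0.353 with an estimated correlation). Thbs4, encoding a thrombospondin of tendon, was listed at 0 in wild type and at 12200, 5027 and 5103 in mdx. Chodl, encoding chondrolectin and placed in the same list, fell 4.87-fold from 28462 ± 1101 to 5955 ± 1454. Its wild-type mean lay above that of Pax7 (8374), so it cannot be read as a tenocyte marker in these libraries. Schwann and nerve markers rose in 10 of 18 cases and Scn7a, a sodium channel gene, fell (camera adjusted p = 0.00294, adjusted p = 0.245 with an estimated correlation). The median log2 fold change was 3.0, and 1.96 after length and GC correction, where 6 rose and 2 fell. The fall of Scn7a was not called without mdx 1, 2 or 3 (limma adjusted p = 0.0672, 0.0626 and 0.0541). Antigen-presenting and dendritic cell markers rose in 6 of 11 cases, among them H2-Aa and H2-Eb1, which encode class II molecules and rose 15.9-fold and 8.35-fold (camera adjusted p = 0.00278, adjusted p = 0.245 with an estimated correlation). Pericyte and smooth muscle markers rose in 6 of 16 cases and Tagln, an actin-binding protein gene chosen after its values were seen, fell (camera adjusted p = 0.024, adjusted p = 0.353 with an estimated correlation). That list did not pass with the stricter filter (camera adjusted p = 0.060), without mdx 1 (0.0715), without mdx 2 (0.0687) or after length and GC correction (0.0555). Neutrophil and mast cell markers rose in 4 of 11 cases, among them Kit, listed at 0 in wild type and at 163, 147 and 92 in mdx (camera adjusted p = 0.0144, adjusted p = 0.353 with an estimated correlation, and 0.112 without wild type 1). A pseudocount of 10 lowered the log2 fold change of Kit from 6.05 to 3.81.

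The remaining lists of blood and fat cells did not pass. None of 8 tested lymphocyte markers was called by limma (camera adjusted p = 0.77; unadjusted p under 0.05 for 0 of them). The T-cell receptor gene Trac was listed at 0 in both wild-type libraries and at 0, 22 and 13 in mdx. Of 9 erythroid and platelet markers, Alas2, encoding the first enzyme of erythroid heme synthesis, rose, listed at 0 in wild type and at 186, 34 and 123 in mdx. Its call ended without mdx 3 (limma adjusted p = 0.0532) and with the replicate number as a block (0.068). The erythroid list did not pass (camera adjusted p = 0.245), except without mdx 2 (0.0311). Its median log2 fold change was 2.99, and −0.51 over the 4 members above 0 in wild type. Of the 4 tested adipocyte markers, Fabp4, Lpl and Pparg rose (limma adjusted p = 0.00684, 0.0253 and 0.035), and the list was too small for camera. None of these 3 was called without mdx 1 (limma adjusted p = 0.0749, 0.128 and 0.0797), mdx 2 (0.0591, 0.114 and 0.112) or mdx 3 (0.0748, 0.0759 and 0.101). Without wild type 2, Lpl and Pparg were not called either (0.0733 and 0.0576), and the log2 fold change of Lpl went from 1.16 to 0.65. That of Fabp4 went from 5.35 to 3.13 without wild type 1 and 7.56 without wild type 2, that of Pparg from 4.12 to 5.35 and 2.90, and that of Alas2 from 5.56 to 6.26 without mdx 2. Pparg was not called after quantile normalization (0.0583), and a pseudocount of 10 lowered its log2 fold change from 4.12 to 2.72 and that of Alas2 from 5.56 to 3.39. Adjusted over each list alone, 7 higher and 1 lower were called for tenocytes, 12 higher and 2 lower for Schwann cells, 6 higher for antigen-presenting cells, 8 higher and 2 lower for pericytes, 5 higher for neutrophils and mast cells and 1 higher for erythroid cells.

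Some genes of necroptosis were called, a smaller share than the 24.9% of all tested genes, and the list as a whole did not pass. Ripk3, encoding the kinase that activates the pathway's executioner (chromosome 14, 55784996 to 55788857), had 1 and 18 normalized counts in wild type and 98, 233 and 104 in mdx 1, 2 and 3. Its log2 fold change was 4.13 (SE 1.09, 95% interval 1.67 to 6.59, limma adjusted p = 0.024), and 2.76 and 5.50 without wild type 1 or 2. Ripk1, encoding the kinase upstream (chromosome 13, 34002363 to 34037147), fell 1.83-fold from 3397 ± 42.4 to 1889.7 ± 421 (log2 fold change −0.87, SE 0.22, limma adjusted p = 0.0203). Mlkl, encoding the executioner that permeabilizes the membrane (chromosome 8, 111311797 to 111338177), was listed at 0 in both wild-type libraries and at 12, 31 and 129 in mdx, and did not pass (limma adjusted p = 0.0516). The call of Ripk3 ended without mdx 1, 2 or 3 (limma adjusted p = 0.0819, 0.111 and 0.0928), and that of Ripk1 without mdx 2 or 3 (0.0835 and 0.0767). With the replicate number as a block, neither Ripk3 (limma adjusted p = 0.0748) nor Ripk1 (0.108) was called. Mlkl passed without mdx 1 (0.0464), with a pseudocount of 1 (0.0455) and in the fit on protein-coding genes (0.0406).

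Of 41 tested necroptosis genes, 5 rose, 4 fell and 32 did not pass, with 5 higher and 4 lower when adjusted over the list alone. The list did not pass (median log2 fold change 0.20, camera adjusted p = 0.73), and its median was 0.11 over the 39 members above 0 in wild type. Besides Ripk3, the genes that rose were Stub1, Tnf, Casp8 and Sharpin, the last pair chosen after their values were seen. Stub1, encoding a ubiquitin ligase, rose 6.82-fold from 57.5 ± 20.5 to 401 ± 105 (limma adjusted p = 0.00438). Tnf, encoding the cytokine that triggers the pathway, was listed at 0 in wild type and at 40, 73 and 91 in mdx (limma adjusted p = 0.0137). Besides Ripk1, the genes that fell were Hsp90aa1, Tlr4 and Tnfaip3, the last chosen after its values were seen. Hsp90aa1, encoding a cytosolic chaperone, fell 3.72-fold from 18126 ± 1665 to 4874 ± 350.1 (limma adjusted p = 7.39e-05), and Tlr4, encoding a receptor for bacterial lipopolysaccharide, 4.75-fold from 1570 ± 165 to 331 ± 50.2. Tnf was not called with the replicate block (limma adjusted p = 0.0785), and a pseudocount of 10 lowered its log2 fold change from 5.05 to 2.90. Macrophage markers were higher in the same mdx libraries, with a median log2 fold change of 5.98.

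Of 24 apoptosis genes, 2 rose and 4 fell, a share close to the 24.9% called over all tested genes. The list did not pass (camera adjusted p = 0.927), and its median log2 fold change was 0.09 although the test's direction was lower. Mcl1, encoding a survival protein, fell 2.11-fold from 12708 ± 1589 to 6005 ± 403 (limma adjusted p = 0.0015), and not after quantile normalization (0.119). Bcl2, encoding another survival protein, rose 2.83-fold (limma adjusted p = 0.0235), without call when wild type 2, mdx 1, mdx 2 or mdx 3 was left out (0.0849 with a log2 fold change of 0.83, against 2.18 without wild type 1, 0.10, 0.0954 and 0.112). Pyroptosis and inflammasome genes rose in 3 of 18 cases, the sensors Nlrp1b, Naip2 and Naip5, each listed at 0 in wild type, with Nlrp1b at 100, 294 and 105 in mdx (camera adjusted p = 0.024, adjusted p = 0.343 with an estimated correlation). The median log2 fold change of the list was 2.71, and 0.18 over the 10 members above 0 in wild type, and macrophage markers were higher in the same mdx libraries (median 5.98). That list did not pass with the stricter filter (camera adjusted p = 0.601), without wild type 1 (0.13), without mdx 2 (0.0512) or with a pseudocount of 10 (0.0568). Naip5 was not called without mdx 2 or mdx 3 (limma adjusted p = 0.080 and 0.0991), with a pseudocount of 10 (0.0548), after quantile normalization (0.0692) or after length and GC correction (0.0532). A pseudocount of 10 lowered the log2 fold changes of Nlrp1b and Naip2 from 6.21 and 5.33 to 3.97 and 3.16. With the replicate number as a block, Bcl2 and Naip2 were not called (limma adjusted p = 0.0857 and 0.0655), and Bcl2 was not called after length and GC correction (0.121). Of 30 p53 targets and senescence genes, 10 rose and 5 fell (camera adjusted p = 0.123). Igfbp3, which binds insulin-like growth factors, was listed at 0 in wild type and at 1655, 2151 and 1817 in mdx, and Btg2, an antiproliferative gene, fell 2.87-fold. TNF and NF-κB targets rose in 11 and fell in 6 of 30 cases (camera adjusted p = 0.279). Nfkbia, encoding the inhibitor of NF-κB, fell 3.0-fold from 3660 ± 86.3 to 1222 ± 119, while Icam1, an adhesion molecule gene, rose 23.4-fold. Adjusted over each list alone, 2 higher and 4 lower were called for apoptosis, 3 higher for pyroptosis, 12 higher and 6 lower for p53 and 11 higher and 6 lower for NF-κB.

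The chromatin side of the comparison was described with the subunits of NuRD, the nucleosome remodelling and deacetylase complex. Chd4, encoding its main ATPase (chromosome 6, 125095981 to 125130591), rose 1.91-fold from 4351 ± 198 to 8335 ± 1001 (log2 fold change 0.93, SE 0.17, limma adjusted p = 0.00424), with all 3 mdx libraries above both wild-type libraries. After length and GC correction its log2 fold change was −0.05 (limma adjusted p = 0.838), and after quantile normalization 1.47 (0.000686). Of 15 subunits, 5 rose, 2 fell and 8 did not pass, with 6 higher and 2 lower when adjusted over the list alone. The complex did not pass as a list (median log2 fold change 0.63, camera adjusted p = 0.279). Chd3, encoding a related ATPase, rose 4.0-fold from 260.5 ± 6.36 to 1048 ± 43.1, and Mta1 rose 2.45-fold. Neither was called after that correction (limma adjusted p = 0.076 and 0.0793). Rbbp7, encoding a histone-binding subunit, fell 2.75-fold from 4790 ± 107 to 1744 ± 116 (limma adjusted p = 0.000538). Gatad2b and Mbd3, which rose, and Mta2, which fell, were chosen after their values were seen.

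Among 35 Polycomb, H3K9 and DNA methylation genes, 8 rose and 1 fell, close to the 24.9% called over all tested genes. The list did not pass (camera adjusted p = 0.588), with 8 higher and 1 lower when adjusted over the list alone. Eed, encoding a core Polycomb subunit, fell 3.84-fold from 1022 ± 22.6 to 267 ± 42.1 (limma adjusted p = 0.00231). Dnmt3a, encoding a DNA methyltransferase, rose 3.43-fold, and Ehmt2, encoding an H3K9 methyltransferase, 2.2-fold. After length and GC correction, the log2 fold changes of Dnmt3a and Ehmt2 were 0.75 and −0.27, and neither was called (limma adjusted p = 0.129 and 0.381). Ehmt2 was also not called with the replicate number as a block (0.0507).

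The make-up of the RNA differed between genotypes. Small nucleolar, Cajal body and nuclear RNAs, which guide the modification and splicing of other RNAs, took 18.5 ± 2.46% of normalized counts in wild type (SD, n = 2) and 0.0849 ± 0.00812% in mdx (SD, n = 3). Of 357 such genes tested, 244 fell in the limma fit, with a median log2 fold change of −5.56. The 8 largest falls under the naming rule were those of Xist and of small nucleolar RNA genes. Snord32a had 74070 and 179376 normalized counts in wild type and 11, 0 and 0 in mdx. Its log2 fold change went from −14.91 to −9.86 after length and GC correction, to −15.55 and −14.28 without wild type 1 or 2 and to −15.81 without mdx 1. Snora52 and Snord67 were listed at 0 in all mdx libraries. Snora65 fell 439-fold from 47432 ± 14496 to 105 ± 21.9 and Snora23 182-fold from 38690.5 ± 5656 to 213 ± 52.7 (limma adjusted p = 7.76e-07 and 8.26e-07).

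Ribosomal protein genes, whose products build the cytosolic ribosome, fell as a group: 72 of 77 fell, 1 rose and 4 did not pass (camera adjusted p = 1.19e-24, adjusted p = 0.343 with an estimated correlation). Members had a median log2 fold change of −2.38 (−1.97 after length and GC correction, with 69 fallen). Adjusted over the list alone, 1 higher and 74 lower were called. Rps3 fell 13.8-fold from 37686 ± 4605 to 2753 ± 512 (limma adjusted p = 7.79e-06), Rpl11 26.8-fold and Rps21 53.4-fold. Their transcripts took 6.71 ± 0.92% in wild type and 1.39 ± 0.253% in mdx. Many of these genes have processed pseudogenes, and small nucleolar RNAs lie within introns of host genes. How reads were divided between such overlapping or similar genes is not given in the sources used here.

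Transcripts of the mitochondrial respiratory chain were lower, and mitochondrial ribosomal RNA differed between libraries. Of 74 nuclear genes of oxidative phosphorylation, 33 fell, 1 (Cox6c, chosen after its values were seen) rose and 40 did not pass (camera adjusted p = 1.80e-09, adjusted p = 0.245 with an estimated correlation). The median log2 fold change was −1.16 (−0.77 after length and GC correction, with 25 fallen), and 2 higher and 35 lower were called when adjusted over the list alone. Uqcrh, encoding a subunit of complex III, fell 19.3-fold from 3037 ± 1106 to 154 ± 41.1 (limma adjusted p = 0.000101), and Sdha, encoding the catalytic subunit of complex II, fell 4.0-fold from 5149 ± 319.6 to 1287 ± 129. Of 8 mitochondrially encoded messenger RNAs, 4 fell (camera adjusted p = 0.0144, adjusted p = 0.513 with an estimated correlation), with 4 lower when adjusted over the list alone. That list did not pass with the stricter filter (camera adjusted p = 0.0757), without wild type 2 (0.126), without mdx 2 (0.0512), after quantile normalization (0.233) or after length and GC correction (0.143), and fry did not call it (adjusted p = 0.0585). Mitochondrial ribosomal RNA took 3.25 and 4.37% of normalized counts in the wild-type libraries and 23.3, 6.58 and 12.2% in mdx 1, 2 and 3.

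Single transcripts took large shares. Lars2, encoding the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123366927 to 123462664), fell 259-fold from 215014 ± 14614 to 829 ± 78.6 (limma adjusted p = 4.31e-08). The unnamed gene Gm26917 (chromosome 17, 39843013 to 39846341), chosen after its values were seen, took 0.419 ± 0.0984% in wild type and 7.36 ± 2.17% in mdx. How reads that map to several places were assigned is not given in the sources used here. Neither the fall of Lars2 nor the rise of Gm26917 can therefore be credited to the gene's own transcript. Of 8 nuclear retained RNAs, 3 fell (camera adjusted p = 0.126, but 0.0218 after length and GC correction; 1 higher and 4 lower when adjusted over the list alone). The fall farthest from 0 was that of Xist (log2 fold change −12.95, and −13.88 without mdx 3), the sex marker described below. Malat1, a long noncoding RNA of nuclear speckles, fell 2.09-fold from 321776 ± 37516 to 153911 ± 14314 and Neat1, the scaffold of paraspeckles, 2.56-fold. Neither was called after quantile normalization (limma adjusted p = 0.476 and 0.682).

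**Figure D3:**
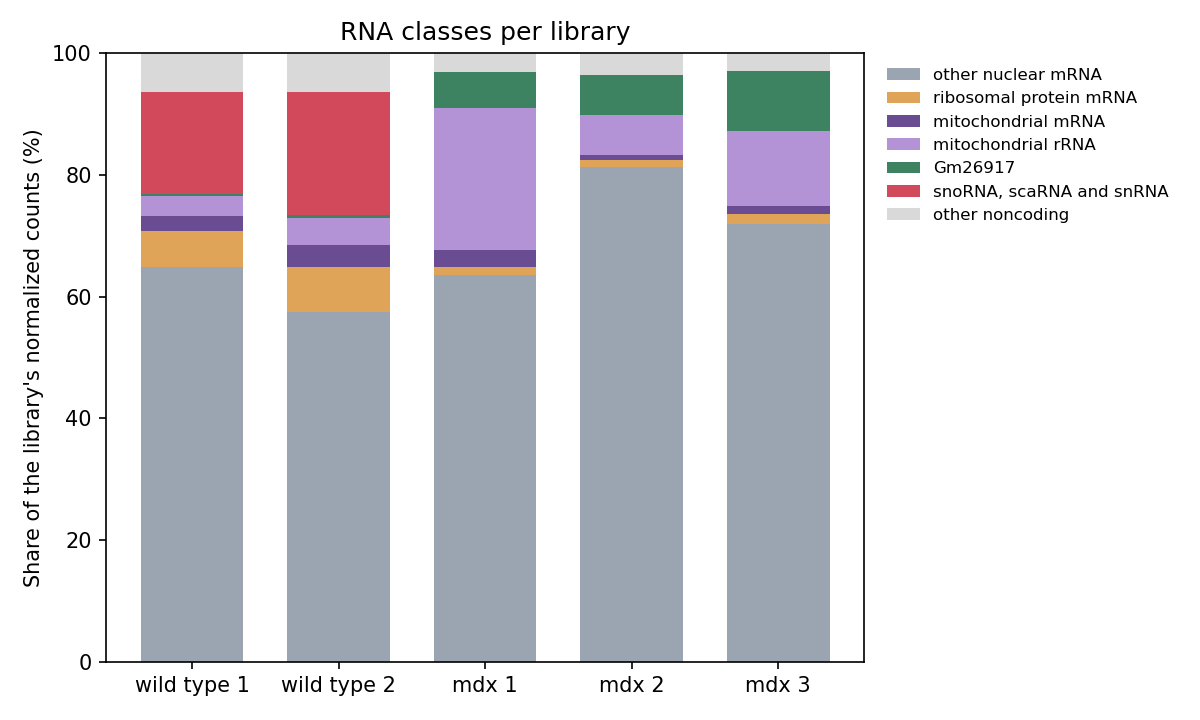
Share of normalized counts (percent) taken by each class of RNA in each of the 2 wild-type and 3 mdx libraries. Small nucleolar and nuclear RNAs and ribosomal protein transcripts took larger shares in both wild-type libraries, and Gm26917 in all 3 mdx libraries.

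Transcripts linked to the sex of the animals separated the genotypes. Xist, the RNA that silences an X chromosome in females, had 30235 and 30176 normalized counts in the wild-type libraries and 0, 0 and 12 in mdx. The Y-linked genes Uty, Eif2s3y, Kdm5d and Ddx3y (the last chosen after its values were seen) summed to 10 and 0 in wild type and to 3444, 2926 and 2298 in mdx. The sex-linked list passed (camera adjusted p = 0.0309, adjusted p = 0.338 with an estimated correlation), with 4 higher and 1 lower of 6, and 4 higher and 1 lower when adjusted over the list alone. It did not pass without wild type 1 (camera adjusted p = 0.076), without mdx 3 (0.0634) or with the replicate number as a block (0.103). Of 9 genes known to differ between mouse strains, 2 rose (camera adjusted p = 0.242; 2 higher when adjusted over the list alone). These were Cyfip2, with 9 and 0 in wild type and 259, 323 and 225 in mdx, and Trim30d, listed at 0 in wild type and at 191, 40 and 133 in mdx. Trim30d was not called with the replicate number as a block (limma adjusted p = 0.0625), and a pseudocount of 10 lowered its log2 fold change from 5.69 to 3.50. It was 6.33 without mdx 2, and that of Cyfip2 went from 5.84 to 7.07 and 4.61 without wild type 1 or 2. By their Xist and Y-linked transcripts, the wild-type libraries were female and the mdx libraries male. Each comparison of mdx with wild type was therefore also a comparison of males with females, and the data cannot tell genotype from sex.

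Fold changes depended on transcript length. Over 13775 protein-coding genes, the median log2 fold change was −1.10 for transcripts of up to 500 bases (47 genes) and 0.71 for those above 8000 bases. It was −0.93 for the 485 genes of 500 to 1000 bases. Ribosomal protein genes, which fell as a group, were kept in these classes. In the longest class, 39.1% of 845 genes rose and 5.8% fell. Across genes, which are not independent replicates, Spearman's rho of the fold change was 0.216 with transcript length and 0.221 with GC content. Among named genes not given above, removal of these trends moved the log2 fold change by over 1.5 times and kept the call at 1.02 for Plec (from 3.30), 0.64 for Sntb2 (from 1.38), 2.56 for Ttn (from 4.08), 1.78 for Stub1 (from 2.77), −1.38 for Ripk1 (from −0.87), 0.90 for Lrp5 (from 2.12), 0.79 for Ltbp3 (from 2.13), 1.76 for Pdgfrb (from 2.71), −2.42 for Neat1 (from −1.36), −5.09 for Snora65 (from −8.78) and −3.69 for Snora23 (from −7.51). Quantile normalization did so at −1.17 for Hsp90aa1 (from −1.89), −0.81 for Btg2 (from −1.52), 1.83 for Utrn (from 1.22) and −1.39 for Chodl (from −2.29).

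**Figure D4:**
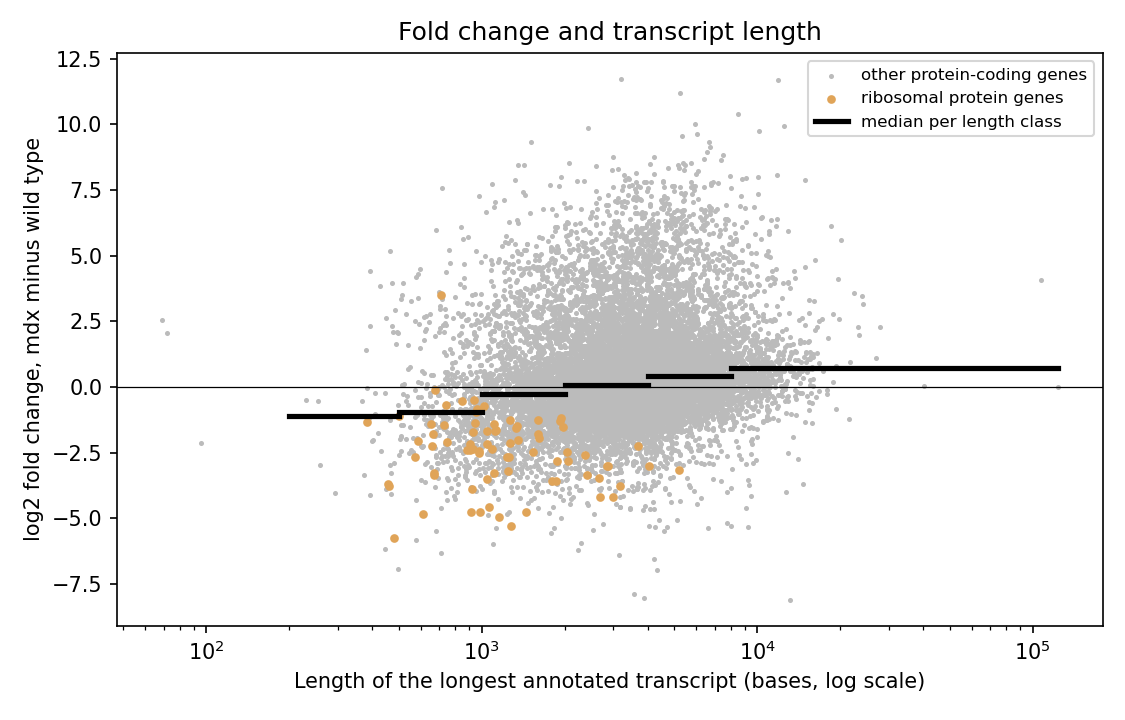
Log2 fold change (mdx minus wild type) of protein-coding genes by the length of their longest transcript in bases; black bars are medians of length classes. The medians go from −1.10 in the shortest class (47 genes) to 0.71 in the longest, with ribosomal protein genes included.

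Signalling pathways that hold satellite cells at rest or activate them were partly higher in mdx. Of 35 Wnt pathway genes, 13 rose and 1 (Wnt4, chosen after its values were seen) fell (camera adjusted p = 0.00229, adjusted p = 0.245 with an estimated correlation). Their median log2 fold change was 1.56, and 0.56 over the 26 members above 0 in wild type. Length and GC correction lowered it to 1.03, with 11 risen and 4 fallen, and the list passed (camera adjusted p = 0.0218). Lrp5, encoding a Wnt coreceptor, rose 4.36-fold from 502 ± 201 to 2111 ± 159, and Ccnd1, encoding cyclin D1, 2.95-fold. Of 26 Notch pathway genes, 11 rose (camera adjusted p = 0.018, adjusted p = 0.338 with an estimated correlation). Notch4, encoding a receptor found in endothelium, had 4 and 5 in wild type and 490, 510 and 462 in mdx, and Notch1 rose 3.43-fold. The Notch list did not pass without wild type 1 (camera adjusted p = 0.0716), with the replicate number as a block (0.0611) or after length and GC correction (0.392), where Notch1 had a log2 fold change of 0.35 (limma adjusted p = 0.227). Endothelial markers were higher in the same libraries, with a median log2 fold change of 7.05.

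Among 44 growth factor and cytokine genes, covering ligands, receptors and signalling components, 15 rose and 3 fell (camera adjusted p = 0.00564, adjusted p = 0.245 with an estimated correlation). In the same mdx libraries, markers of fibro-adipogenic progenitors (median log2 fold change 3.22), pericytes (2.21) and macrophages (5.98) were higher, and Pdgfrb is also in the pericyte list. Pdgfrb, encoding a receptor of mesenchymal cells, rose 6.55-fold from 132 ± 60.8 to 841 ± 162. Lrig1, Socs3 and Tnfrsf12a, which fell, were chosen after their values were seen. After length and GC correction this list did not pass (camera adjusted p = 0.174). Genes of TGF-β and BMP signalling went both ways, with 14 of 42 risen and 6 fallen (camera adjusted p = 0.245). Skil, encoding an inhibitor of the pathway, fell 4.57-fold from 9766 ± 1719 to 2128 ± 238, and Ltbp3, encoding a protein that binds latent TGF-β, rose 4.37-fold. Adjusted over each list alone, 13 higher and 3 lower were called for Wnt, 11 higher for Notch, 16 higher and 4 lower for growth factor and cytokine genes and 15 higher and 7 lower for TGF-β.

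Of the immune lists, complement passed, with 7 of 20 genes risen and 2 (Serping1 and Cfb, chosen after their values were seen) fallen (camera adjusted p = 0.0149, adjusted p = 0.279 with an estimated correlation). C3, encoding the central complement component, rose 13.7-fold from 174 ± 68.6 to 2329.7 ± 447 (limma adjusted p = 8.22e-05), and C1qb, a macrophage product, was listed at 0 in wild type and at 238, 648 and 481 in mdx. Of the 7 that rose, 3 are also in the macrophage list, which was higher in the same libraries (median log2 fold change 5.98). Interferon response genes rose in 10 and fell in 7 of 53 cases (camera adjusted p = 0.35), Sp100 rising 9.13-fold. Class I presentation genes rose in 5 and fell in 3 of 21 cases (camera adjusted p = 0.496). Erap1, encoding a peptidase that trims antigens, fell 3.14-fold from 2159 ± 266 to 684 ± 59.2, and Nlrc5, encoding an activator of class I genes, rose 5.16-fold. The call of Nlrc5 ended without mdx 2 (limma adjusted p = 0.0649), without mdx 3 (0.065) and after length and GC correction (0.0959) or with the replicate number as a block (0.0844). Adjusted over each list alone, 10 higher and 3 lower were called for complement, 10 higher and 7 lower for interferon and 6 higher and 4 lower for class I presentation.

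Cholesterol synthesis genes were lower in mdx, with 9 of 24 fallen (camera adjusted p = 0.000256, adjusted p = 0.343 with an estimated correlation). Their median log2 fold change was −1.11. In the same mdx libraries, endothelial (median 7.05) and macrophage markers (5.98) were higher, and the shares of small nucleolar and ribosomal protein transcripts given above were lower. Insig1, encoding a sterol sensor partner, fell 3.15-fold from 1914 ± 596 to 599 ± 115 (limma adjusted p = 0.00368). Antioxidant genes fell in 13 and rose in 4 of 31 cases (camera adjusted p = 0.024, adjusted p = 0.343 with an estimated correlation, and camera adjusted p = 0.0673 after quantile normalization). Gpx3, encoding a glutathione peroxidase, fell 8.09-fold from 35569.5 ± 6289.7 to 4478 ± 1170.0, and Prdx1, encoding a peroxiredoxin, 3.08-fold. Glycolysis genes rose in 3 and fell in 5 of 27 cases (camera adjusted p = 0.306), with Ldha, encoding lactate dehydrogenase A, falling 3.09-fold. Fatty acid genes rose in 7 and fell in 8 of 37 cases (camera adjusted p = 0.605), with Ucp2, encoding a mitochondrial carrier, rising 14.0-fold. Adjusted over each list alone, 11 lower were called for cholesterol, 5 higher and 15 lower for antioxidants, 3 higher and 5 lower for glycolysis and 8 higher and 8 lower for fatty acids.

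The list of immediate early and heat shock genes passed as lower in mdx. Of its 36 tested genes, 17 fell and 4 rose (camera adjusted p = 0.018, adjusted p = 0.513 with an estimated correlation). The median log2 fold change was −0.65, and −1.01 after length and GC correction. Endothelial (median 7.05) and macrophage markers (5.98) were higher in the same mdx libraries, and the make-up of the RNA differed as given above. Atf3, encoding a stress transcription factor, fell 3.45-fold from 5510 ± 694 to 1594 ± 155, and Ier5 rose 5.14-fold from 253 ± 48.1 to 1301 ± 135. The list did not pass without mdx 2 (camera adjusted p = 0.0758) or after quantile normalization (0.819), and fry did not call it (adjusted p = 0.0629). Genes of the unfolded protein response fell in 7 and rose in 2 of 29 cases (camera adjusted p = 0.774, with the test's direction lower and a median of 0.28). Dnajb9, encoding a chaperone cofactor of the endoplasmic reticulum, fell 5.17-fold. Autophagy and lysosome genes rose in 5 and fell in 8 of 39 cases (camera adjusted p = 0.142, but 0.0187, lower in mdx, after length and GC correction), among them Grn, encoding progranulin, which rose 3.62-fold. Adjusted over each list alone, 6 higher and 19 lower were called for immediate early and heat shock genes, 2 higher and 7 lower for the unfolded protein response and 7 higher and 9 lower for autophagy.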

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

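Pseudocounts of 1 and 10, quantile normalization, length and GC correction, the fit on protein-coding genes and library weights were tests chosen only after the results were seen. Calls from the count model, from limma-voom and from libraries thinned to equal depth were not run, since they need raw counts. Labels gave replicate numbers 1 and 2 in both genotypes, but across genes same-numbered libraries did not deviate together (correlations −0.0138 and −0.0173). The deviations of 2 wild-type libraries mirror each other, so these values are not independent. They do not exclude a shared day or preparation, and no pairing is stated in the sources used here. With the replicate number as a block, 1163 genes were higher and 860 lower, and 2010 of the 4527 calls were kept. The remaining mdx library was alone in its block, so this fit compared the genotypes only in the libraries numbered 1 and 2. The block terms also left less information on the spread between libraries. Calls that ended with the block can therefore reflect the lost library or the lost precision, and which of them did so was not tested. The Notch list (camera adjusted p = 0.0611) and the sex-linked list (0.103) did not pass with the block. With a minimum fold of 1.5 the counts were 1516 and 858. Leaving out 1 library gave 1450 to 3308 higher and 1112 to 1853 lower genes and 20 to 23 lists. Where 1 wild-type library was left, it was assumed to vary like the mdx libraries. Length and GC correction gave 1719 higher genes, with 2976 of 4524 calls kept and 199 changing sign, and a median log2 fold change of −0.09 over all genes, against 0.000148 after quantile normalization. Among named genes, leaving out 1 library ended 68 calls over the 5 fits, length and GC correction 18 besides those that turned, quantile normalization 8 and the replicate block 23. Trimmed-mean and upper-quartile scaling kept 4450 and 4435 calls with 0 sign changes. Of the 43 lists, 0 passed camera with an estimated correlation, a version with little power for so few libraries. Fry, which compares with no other genes, gave adjusted p = 0.0442 for necroptosis, 0.00851 for NuRD, 0.0233 for chromatin repressors, 0.00685 for dystrophin-associated proteins, 0.0215 for nuclear retained RNA, 0.00118 for p53 targets, 0.0449 for strain-linked genes, 0.0205 for TGF-β and 0.0221 for NF-κB targets, and did not call immediate early and heat shock (0.0629) or mitochondrially encoded genes (0.0585).

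Directions turned in these cases, and the cause was not tested. After length and GC correction the tests pointed lower for necroptosis (camera adjusted p = 0.714), NuRD (0.688), chromatin repressors (0.355), dystrophin-associated proteins (0.97) and TGF-β (0.891), and log2 fold changes were −0.053 for Chd4, −0.50 for Pax7 and −0.27 for Ehmt2. Quantile normalization turned apoptosis (0.858), satellite cell identity (0.395) and the unfolded protein response (0.652), and the stricter filter turned apoptosis (0.981). The fit on protein-coding genes turned lymphocyte markers (0.991), and fry turned apoptosis (0.211) and fatty acid genes (0.507). Single libraries turned lymphocyte markers (0.712 without wild type 1, range 0.247 to 0.973), the unfolded protein response (0.984, range 0.357 to 0.984), fatty acid genes (0.955 without wild type 2, range 0.45 to 0.955), class I presentation (0.894, range 0.322 to 0.894) and apoptosis (0.929 without mdx 1, range 0.63 to 0.973). None of these lists passed as reported. Depth is known only as an estimate, and genes near 10 normalized counts have folds that depend on the pseudocount.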

Other observations

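The tests of drop-out in wild type and of length and GC content were chosen only after values bearing on them had been seen, and so was the list of imprinted genes. The drop-out test first covered called markers and was replaced by one over markers called or not, since a call selects for low wild-type values. The tests of linkage and sex were set before the data were examined. The second marker lists were written after the first lists had been seen to rise, but before the values of their own genes were.

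Imprinted genes, which are expressed from 1 parental allele, changed in both directions. Of 21 tested, 11 rose and 4 fell, with a median log2 fold change of 1.0. Camera gave an unadjusted p = 0.0845, so the list did not pass. Plagl1, encoding a zinc finger factor of the imprinted network, had a log2 fold change of 4.91 (limma adjusted p = 2.36e-05), and Peg3 of 1.07. The noncoding RNA Rian had −1.61 (from 10241.5 ± 6056 to 3129 ± 906) and Mirg −2.92 (from 2031.5 ± 1867 to 203 ± 23.1). Both differed widely between the wild-type libraries. After length and GC correction, 8 rose and 5 fell, with a median of 0.38.

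Calls made up 24.9% of tested genes. Linkage to Dmd was not seen to add to them: genes within 20 Mb of it were called 1.11 times as often as genes elsewhere (Fisher's exact p = 0.422). The groups differed in Xist (log2 difference −12.9) and in the Y-linked sum (9.19), so sex may contribute to any call. Of the calls, 4373 lay outside X and Y, and 26.8% of X-linked genes were called against 24.8% of genes off X and Y (Fisher's exact p = 0.297), which does not separate sex from genotype. Genotype stays open and untested against sex and library composition.

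Markers of other cell types were higher in mdx although the cells had been sorted by FACS with a gate not given in the sources used here, and means reached 25807 for Col1a2 and 8264 for Lyz2 beside 12502 for Pax7. Cells of other types in the mdx sorts are a candidate explanation: in second lists of such markers the lowest median log2 fold change was 2.31 (endothelial 4.82, macrophage 4.70), and 81.6% of 49 genes (66.7% of mesenchymal ones) were higher in each mdx library than in both wild-type libraries. Called higher and lower in these lists were 11 and 0 of 15 endothelial, 15 and 1 of 19 macrophage and 7 and 3 of 15 mesenchymal genes. Loss of low transcripts from the wild-type libraries was checked by comparing markers with genes matched on mdx level. Of 154 markers, called or not, 42.2% were under 10 in both wild-type libraries against 9.55% of matched genes. The difference was 32.7 percentage points (Fisher's exact p = 2.35e-23), with co-expressed genes counted as independent. The markers had already been seen to rise, which makes lower wild-type values likely in itself. Such a comparison shows that genes at the same mdx level were under 10 less often and does not decide whether loss contributed. Expression of these genes by dystrophic satellite cells themselves stays open and was not tested, and in wild type 18 of 22 fibro-adipogenic, 10 of 29 macrophage and 8 of 22 endothelial markers had means of at least 10, while 2, 17 and 8 were at 0 in both libraries.

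Ribosomal protein transcripts were lower in mdx. Their median log2 fold change differed by −1.81 from that of genes matched on length and GC content (permutation p = 0.0001, the smallest that 10000 draws can give). Lengths were those of the longest annotated transcript, 3183 bases for Rps3, which may not be the one measured. The draws also treated genes with an estimated correlation of 0.679 as independent. Removal of the length and GC trends moved the ribosomal protein median from −2.38 to −1.97, with 69 of 77 genes called lower and 1 higher. These values argue against the trend, as measured on the longest transcripts, accounting for all of the fall. How much it accounts for on the lengths actually sequenced was not decided. Small nucleolar RNAs fell in the same libraries, by a median of −5.56 on the log2 scale. A difference in RNA handling, in sex or in genotype stays open and was not tested. Any of them would separate the same libraries, so these data cannot tell them apart.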
